A study of Hypomesus transpacificus with 20 samples.

How the data were processed

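RNA from whole delta smelt (Hypomesus transpacificus) was hybridised to a custom 1-colour Agilent oligonucleotide array. Per the labels' protocols, fish were held for 24 h to acclimatise and then exposed for 96 h to the pyrethroid insecticide permethrin, or kept as controls. The exposures are named by what was measured in the water, which was 4.84 ug/L in the highest, then 2.56, 1.37 and 0.69 ug/L. Each of the 5 groups had 4 arrays, 20 in all. Per the labels' protocols, frozen whole fish were homogenised in Trizol, RNA was cleaned on columns with DNase digestion, and Cy3 labelling reactions were run at the same time for all samples. The labels name each array as whole fish with a replicate code such as 2A1 and do not say what the letter stands for, whether fish of a group shared a tank, or whether 1 array is 1 fish. An array is called a fish below, and p-values measure the spread between these arrays.

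The deposited scanner files hold, per the file headers, the output of Agilent Feature Extraction 11.5.1.1, in which each spot has a processed signal, an intensity on a linear scale after background subtraction, together with its median signal, the local background and spot flags. Each array carried 38235 spots, of which 1417 were controls and 36818 were probes with 1 spot each. The scanner files name these probes only by a design number, and the reference table used here lists genes of the species without pairing them to probes. No probe therefore has a gene name here. The gene lists and tissue marker lists fixed for this study (detoxification, nervous system, muscle and others) could not be tested, and neither could the position of any probe in the genome be given. The authors' deposited value table is on a log2 scale. The largest absolute median of a probe over its 20 values was 5e-07, so the authors had centred each probe on its median. How the authors normalised the arrays before centring is not given in the sources used here. Across probes, the table correlated with the scanner values, centred in the same way, with r from 0.952 to 0.994 on 19 arrays and with r = 0.657 on the array of the 2.56 ug/L fish 11B2. The medians of its 20 columns ran from -0.0633 (2.56 ug/L 11B2) to 0.0546 (1.37 ug/L 10C4).

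The signals were taken to log2 and each array's 75th percentile was subtracted. Spots marked as non-uniform or as population outliers were left out, and saturated spots were kept. A probe was tested where its spot was well above background on at least 4 of the 20 arrays, which held for 33464 probes (90.9%). One mean per group was fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted over the tested probes by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. From this fit came each concentration against the controls, the 6 differences between concentrations and an F test of any difference. A trend was fitted as a slope per ug/L of measured concentration, with controls at 0. These tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule was to name, among annotated genes with 1 probe each, up to 10 rises and 10 falls at 4.84 ug/L (past the threshold, without overlap between the 4 exposed and the 4 control arrays) and for the trend, fewer at each lower concentration, and members of the gene lists. As no probe could be tied to a gene, only its part for 4.84 ug/L was followed, on probes with all 8 spots measured, and the 2 largest rises and the 2 largest falls are named by probe. The restriction to 1 probe per gene could not be applied.

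On simulated data with the means and spreads of the 33464 probes, in which 50 probes at each of 4 sizes were changed, the fit of 4.84 ug/L against control recovered 22 of 50 probes changed 2-fold, 45 of 50 changed 4-fold, 48 of 50 changed 8-fold and 49 of 50 changed 16-fold, with 10 false calls. The trend fit recovered 26, 46, 48 and 48 of 50 at those sizes, with 10 false calls. Every value in these simulations was drawn independently. Real probes with consecutive numbers varied together across the fish (median correlation 0.63), so the false calls of the simulations do not describe the real arrays. The number of arrays limits the precision: the median residual SD of a probe was 0.34 on the log2 scale, and 0.56 among the 8366 dimmest probes.

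The arrays lay on 5 slides of 4 arrays, taken from the scan record in the file headers. On 1 slide (slide 3) the identifier in the headers differed from that in the file names and was that of slide 5. The slides were told apart by scan record, and no array correlated with another above a Spearman rho of 0.985. Each slide held 3 or 4 of the groups, so slide could be fitted as a block. Slides 1, 3 and 4 held both a control and a 4.84 ug/L array, and differences within these slides are given. The measures in the rest of this paragraph were added after the data were seen. A pattern across fish was measured on probes chosen without them, among those measured on all arrays. In each of 16 draws, 1 control and 1 fish at 4.84 ug/L were set aside, the 500 probes with the highest and the 500 with the lowest moderated t between the remaining 3 controls and the remaining 3 exposed fish were taken, and each fish not used was placed on a scale where 0 is the mean of those 3 controls and 1 the mean of those 3 exposed fish. A further held-out estimate chose 500 probes per direction in the same way on 2 controls and 2 fish at 4.84 ug/L in 36 draws and measured changes in the other fish. Draws share fish and are not independent.

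Alternatives were quantile normalisation, median centring, normexp background correction with an offset of 50 followed by quantile normalisation, no filter on dim probes, only probes well above background on all 20 arrays, outlier spots kept, slide as a fixed or a random block (duplicateCorrelation, statmod 1.5.0), fish of a group with the same letter in their code as a random block, array weights, eBayes with trend and robust settings, only the 8 arrays of the groups compared, the authors' deposited value table, an adjusted p of 0.1, a minimum change of 1.5-fold, other codings of concentration, and each array left out in turn. Normexp used the median signal of each spot, since the mean signal was not analysed here. The value table was used without removing outlier spots. A fit without the arrays 11B2 and 10C4 together, one with the letter of the code as a block shared between groups, and a trend without the 4.84 ug/L arrays were added after the data were seen. Figures were drawn with matplotlib 3.10.9.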

Results

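Gene expression was measured in whole delta smelt after 96 h in permethrin at 4 measured concentrations, to find which transcripts differ from control fish and whether the response grows with concentration. There were 4 arrays in each of the 5 groups. Between 82.03% and 90.26% of the 36818 probes were well above background on 19 of the arrays. On the array of the 2.56 ug/L fish 11B2 the share was 99.72%, and the SD of its log2 signals was 2 against 2.77 to 3.02 on the other arrays. Rank correlations of each array with the others of its group averaged 0.918 for 11B2 and 0.949 to 0.977 for the rest.

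The trend test called probes in both directions, and called none when the highest concentration was left out. With all 5 groups, 5558 of 33464 probes (16.6%) had a slope with measured concentration that passed limma's test at an adjusted p of 0.05, 2888 rising and 2670 falling. In the rising set the median log2 difference from the controls was -0.08 at 0.69 ug/L, 0.28 at 1.37 ug/L, 0.48 at 2.56 ug/L and 0.72 at 4.84 ug/L. In the falling set it was 0.10, -0.23, -0.41 and -0.75 at the same concentrations. At 0.69 ug/L both medians thus lay on the opposite side of the controls from the trend. Those controls include 2D4, whose place on the held-out scale was 0.68, against -0.15 to 0.16 for the other controls. The 0.69 ug/L fish lay between -0.07 and 0.19 on that scale. Whether 2D4 alone gave these signs was not tested. Group means increased at every step from control to 4.84 ug/L for 521 of the rising probes (18.0%) and decreased at every step for 351 of the falling ones (13.1%). These medians and shares describe probes chosen by the slope itself, which favours such an order, and are no further test of it. Without the 4.84 ug/L arrays, a fit added after the data were seen, limma's trend test called 0 probes (lowest adjusted p 0.074), with 6935 at an unadjusted p under 0.05 (20.7%). Only 16 arrays and concentrations up to 2.56 ug/L remained in that fit, so its slopes were less precise. Its lack of calls therefore neither shows a growth below 4.84 ug/L probe by probe nor excludes one. With all arrays and slide as a fixed block the trend test called 4717 probes. Without the 4.84 ug/L fish 12C3 it called 3373, the only array whose loss moved this count by more than 1.5 times.

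The largest rises at the highest concentration belonged to a pair of consecutively numbered probes, whose gene is not known here. CUST_8948_PI428861894 measured 0.24 ± 2.33 in controls (log2 signal relative to the array's 75th percentile, mean ± SD, n = 4), -1.19 ± 0.49 at 0.69 ug/L, 1.19 ± 2.54 at 1.37 ug/L, 2.90 ± 1.71 at 2.56 ug/L and 5.45 ± 0.35 at 4.84 ug/L. Its log2 change at 4.84 ug/L was 5.21 (SE 1.13, limma adjusted p = 0.021), which is 37.0-fold. With 1 array left out this change ran from 4.63 (without control 2A1) to 6.34 (without control 2D4). The change at 2.56 ug/L, 2.66 (SE 1.13, limma adjusted p = 0.27), and those at 1.37 and 0.69 ug/L did not pass. The slope was 1.27 per ug/L (SE 0.22, limma adjusted p = 0.0018) and passed with each array left out in turn. CUST_8947_PI428861894 followed the same course, with 0.63 ± 2.32 in controls and 5.74 ± 0.36 at 4.84 ug/L, a log2 change of 5.11 (SE 1.10, limma adjusted p = 0.021). Both were well above background on all arrays. The wide SD of the controls came from 1 fish: for CUST_8948_PI428861894 the control 2D4 read 3.64, and the other controls read -1.49, -0.23 and -0.97. Within the slides that held a control and a 4.84 ug/L fish, that probe was higher in the exposed fish by 5.40 (slide 1), 1.55 (slide 3, the slide of 2D4) and 6.46 (slide 4). Its choice without overlap fixed the sign of these differences. Without control 2A1, 2B1 or 2C1, or without 12C3 of the 4.84 ug/L group, both probes lost the call against control; their adjusted p by limma then ran up to 0.091 and 0.09.

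The largest falls were those of CUST_1082_PI428861894 and CUST_16659_PI428861894. CUST_1082_PI428861894 measured 1.39 ± 1.61 in controls (mean ± SD, n = 4), 1.71 ± 1.66 at 0.69 ug/L, 0.36 ± 2.08 at 1.37 ug/L, -1.35 ± 2.57 at 2.56 ug/L and -2.92 ± 0.39 at 4.84 ug/L. Its log2 change at 4.84 ug/L was -4.31 (SE 1.18, limma adjusted p = 0.039), and its slope was -1 per ug/L (SE 0.21, limma adjusted p = 0.0042). CUST_16659_PI428861894 went from 0.97 ± 2.49 in controls to -3.05 ± 0.38 at 4.84 ug/L, a log2 change of -4.02 (SE 1.12, limma adjusted p = 0.042), with a slope of -0.97 per ug/L (SE 0.21, limma adjusted p = 0.0049). At 4.84 ug/L their signals were 5.03% and 6.15% of the control level. The control 2D4 read low on both probes. On CUST_16659_PI428861894 it read -2.55, barely above the -2.56 of the 4.84 ug/L fish 12B4, while the other controls read 0.96 to 2.93. On CUST_1082_PI428861894 it read -0.8 and the other controls 1.21 to 2.88. With 1 array left out, the change of CUST_1082_PI428861894 ran from -5.04 (without 2D4) to -3.82 (without 2B1). That of CUST_16659_PI428861894 ran from -5.19 to -3.37, without the same arrays. The size depends on the treatment of background: after normexp the log2 changes were -2.61 and -2.43 and the slopes -0.61 and -0.59. Within slides 1, 3 and 4 the exposed fish was lower than the control by -5.28, -2.26 and -4.11 for the first probe and by -5.49, -0.93 and -3.97 for the second. The choice of both probes without overlap fixed the sign of these differences. The slopes passed with each array left out in turn. The calls against control at 4.84 ug/L were weaker: CUST_1082_PI428861894 kept its call in 12 of the 20 fits without 1 array (limma adjusted p up to 0.13, without control 2A1) and CUST_16659_PI428861894 in 8 of 20 (up to 0.15, without control 2A1).

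**Figure D1:**
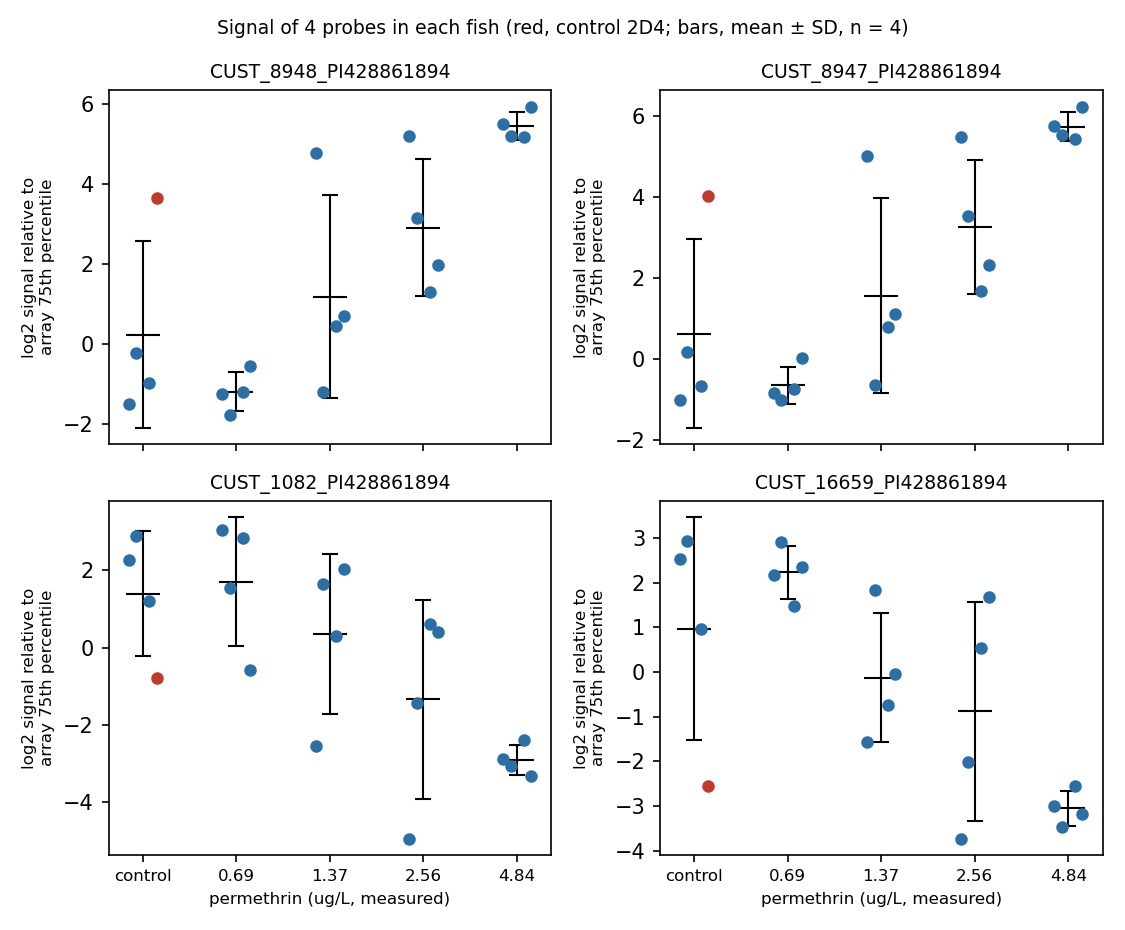
Log2 signal relative to the array's 75th percentile (vertical axis) of the 4 named probes in each fish, by measured permethrin concentration in ug/L (horizontal axis); points are fish, with the control 2D4 in red, and bars are the mean ± SD of 4 fish. The 4.84 ug/L fish lie close together, at 5.17 to 5.93 for CUST_8948_PI428861894, while controls and the middle concentrations spread over several log2 units.

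At 4.84 ug/L, 2141 probes (6.4% of those tested) differed from the controls by limma's test, 1188 higher and 953 lower. The median log2 change was 0.93 among those higher (quartiles 0.71 and 1.19) and -1.05 among those lower (quartiles -1.59 and -0.77). Under this treatment of background, 156 probes were lower and 39 higher by over 4-fold; these were not counted after normexp, which made the named falls smaller. The calls were denser among bright probes, at 11% of the 8366 brightest and 1.8% of the 8366 dimmest probes tested. Of the called probes with all 8 spots measured, 1694 (82.2%) had no overlap between the 4 exposed and the 4 control fish, a share raised by their selection. Over all tested probes with these 8 spots measured the share without overlap was 15.2%, and chance gives 2.86% on average. As probes vary together, the share in a single comparison can stray from that average. Within slides the median difference, exposed minus control, of the probes called higher was 1.12 on slide 1, 0.33 on slide 3 and 0.84 on slide 4, and for those called lower it was -1.13, -0.55 and -1.16. The same fish served to call these probes, which favours such signs, so the medians are no separate test. With slide as a fixed block 1463 probes were called. The count rested on single fish: it was 0 without control 2A1, 199 without 2B1, 547 without 2C1 and 4205 without 2D4, and it was 1297 without 12A1, 1036 without 12A2, 554 without 12B4 and 211 without 12C3 of the exposed fish. With only the 8 arrays of both groups in the fit it was 557, and with array weights 6468. The balance of directions was not stable either. More of the called probes were higher after normexp (1367 and 752 lower), with the authors' table (1416 and 940) and without 2C1 (362 and 185). Fewer were higher than lower with the 8 arrays (168 and 389), without 2B1 (72 and 127), without 12C3 (69 and 142) and with array weights (3139 and 3329).

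No probe passed at the lower concentrations. At 2.56 ug/L against control, limma called 0 probes (lowest adjusted p 0.16), with 5329 at an unadjusted p under 0.05, which is 15.9% of the tested probes. At 1.37 ug/L it called 0 (lowest adjusted p 0.39), with 3387 at an unadjusted p under 0.05 (10.1%). At 0.69 ug/L it called 0 (lowest adjusted p 0.46), with 556 at an unadjusted p under 0.05 (1.7%). The count at 2.56 ug/L became 309 without control 2D4, 282 higher and 27 lower, and 2, 1 and 1 without control 2B1, 11A3 and 11C4. At 1.37 ug/L it became 23 without the fish 10B3 of that group, 2 without control 2B1 and 3 without control 2D4, and at 0.69 ug/L 1 without control 2B1 and 2 without 9B3. With array weights 7 probes were called at 1.37 ug/L.

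Direct tests between concentrations placed the 4.84 ug/L fish apart from the 0.69 ug/L fish. By limma's test 4323 probes differed between 4.84 and 0.69 ug/L, 2259 higher and 2064 lower, of which 3845 of those with all 8 spots measured (94.1%) had no overlap. As called probes are chosen for their difference, the share over all tested probes with these 8 spots measured is the one to set against chance. It was 21.8%, where chance gives 2.86% on average. In comparisons with 0 calls that share ran from 1.7% (0.69 ug/L against control) to 9.7% (4.84 against 1.37 ug/L). CUST_8948_PI428861894 was higher at 4.84 than at 0.69 ug/L by 6.64 (SE 1.13, limma adjusted p = 0.0036) and CUST_16659_PI428861894 was lower by -5.29 (SE 1.12, limma adjusted p = 0.0069). This count fell to 2677 without 9B1, 2637 without 9B3, 2875 without 12B4 and 2295 without 12C3. Between 2.56 and 0.69 ug/L, 310 probes passed, 271 higher and 39 lower. That count did not hold under other choices: it was 0 without 11B2, 3 after quantile normalisation (2 higher, 1 lower), 16 after median centring (11 higher, 5 lower) and 0 after normexp, and it was also 0 without each of 9B1, 9D1, 10D2, 11D1, 12A2 and 12B4 in turn, 1, 2 and 4 without 11A3, 9B3 and 9A2, and between 110 and 174 without 2C1, 10A2, 10C4 or 12A1. It was 849 without control 2D4 and 2450 without 11C4. Under the 75th-percentile scaling the median log2 difference of all probes between these groups was 0.13, and under median centring it was 0.01. Limma called 0 probes for 4.84 against 1.37 ug/L, with 4656 at an unadjusted p under 0.05. For 4.84 against 2.56 ug/L it called 0, with 3473 at an unadjusted p under 0.05. For 2.56 against 1.37 ug/L and for 1.37 against 0.69 ug/L it called 0, with 3813 and 3447 at an unadjusted p under 0.05. These 4 counts reached 5, 1, 3 and 43 at most with 1 array left out; the 5 came without 10B3 or without 12C3, the 1 without 11A3, the 3 without 10B3 or without 11C4 (2 without 11A3), and the 43 without 10B3 (2 without 9B3). The limma F test of any difference among the 5 groups called 1772 probes, with counts from 0 (without 12B4) to 3108 (without control 2D4) when 1 array was left out. It stayed within 1.5 times of that count in 6 of the 20 such fits, and with slide as a fixed block it was 1088.

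The mean places of the fish at 1.37 and 2.56 ug/L, on probes chosen without them, lay between those of the controls and the 4.84 ug/L fish, a measure added after the data were seen that was not tested against either end. On the scale from the controls (0) to the 4.84 ug/L fish (1), the mean place was 0.19 ± 0.35 for controls (SD, n = 4), 0.03 ± 0.12 at 0.69 ug/L, 0.43 ± 0.28 at 1.37 ug/L, 0.56 ± 0.20 at 2.56 ug/L and 0.83 ± 0.07 at 4.84 ug/L. Only the middle 3 groups never served to choose probes. Among these, 2.56 exceeded 0.69 ug/L by 0.54 with no overlap (exact permutation test, two-sided, p = 0.0286, adjusted over 3 tests 0.0857), 1.37 exceeded 0.69 ug/L by 0.41 (exact permutation test, p = 0.0571, adjusted 0.0857), and 2.56 exceeded 1.37 ug/L by 0.13 (exact permutation test, p = 0.486). The smallest p that 4 against 4 can give is 0.0286, and no test passed after adjustment. Single fish departed from their groups: the control 2D4 was placed at 0.68, against -0.15 to 0.16 for the other controls, and at 1.37 ug/L the fish ran from 0.11 (10B3) to 0.79 (10A2). The places of 10A2 and of the 2.56 ug/L fish 11A3 (0.82) were within the range of the 4.84 ug/L fish, 0.75 to 0.93, and that of 10B3 within the range of the other controls.

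**Figure D2:**
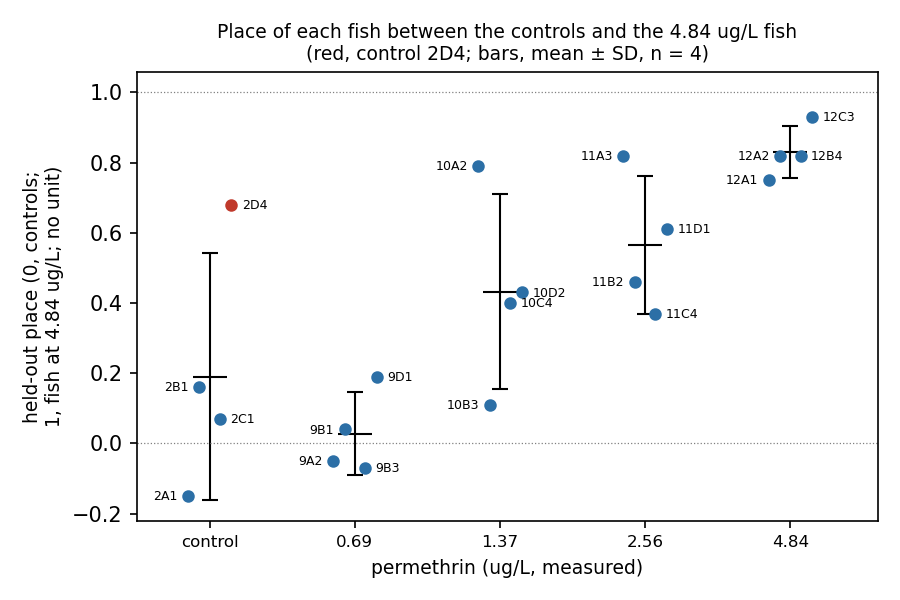
Held-out place of each fish (vertical axis, no unit; 0 is the mean of the controls and 1 the mean of the 4.84 ug/L fish used to choose the probes) by measured permethrin concentration in ug/L (horizontal axis); points are fish with their replicate codes, and bars are the mean ± SD of 4 fish. The 4.84 ug/L fish lie between 0.75 and 0.93, the 0.69 ug/L fish between -0.07 and 0.19, and the control 2D4, in red, at 0.68.

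With probes chosen, likewise after the data were seen, on 2 controls and 2 fish at 4.84 ug/L and measured in the rest, the probes chosen as higher had a median log2 change of 0.64 in the other 4.84 ug/L fish (mean of 36 draws, range 0.28 to 1.02), 0.54 at 2.56 ug/L (0.19 to 0.77), 0.21 at 1.37 ug/L (-0.08 to 0.49) and -0.29 at 0.69 ug/L (-0.80 to 0.04). For probes chosen as lower the values were -0.94 (-1.26 to -0.58), -0.38 (-0.68 to 0.04), -0.34 (-0.70 to 0.06) and 0.25 (-0.17 to 0.77). Control 2D4 took part in these draws, and whether it gave the signs at 0.69 ug/L was not tested.

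Changes against the controls were compared across probes, which are not independent replicates, and the comparisons share the 4 control arrays. The correlation of log2 changes was 0.677 between 2.56 and 4.84 ug/L, 0.559 between 1.37 and 4.84 ug/L and 0.495 between 1.37 and 2.56 ug/L, where simulated unchanged groups with shared controls gave 0.500, 0.498 and 0.499. The covariances of 0.164, 0.127 and 0.092 exceeded the simulated ones by 0.101, 0.064 and 0.030. With the controls split 2 and 2 the correlations averaged 0.404 (0.194 to 0.549 over the splits), 0.294 (0.044 to 0.497) and 0.183 (0.053 to 0.281). For 0.69 ug/L the correlations with 1.37, 2.56 and 4.84 ug/L were 0.274, -0.001 and -0.026, below the simulated 0.501. With split controls they averaged -0.105 (-0.284 to 0.041), -0.274 (-0.453 to -0.162) and -0.229 (-0.506 to -0.015). Control 2D4 took part in every split, and whether it gave the negative signs was not tested. The covariances with 0.69 ug/L lay below the simulated ones by -0.032, -0.063 and -0.067.

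In a principal component analysis, scores followed concentration most clearly once the array of 11B2 was left out after the data were seen. Its score on the first component of all 20 arrays was 154.2. Over the other 19 arrays the first component held 27.6% of the variance and correlated with measured concentration (Pearson r = 0.81, permutation p = 5e-05, adjusted over 3 components 0.00015; Spearman rho = 0.79, permutation p = 0.00013, adjusted 0.00039). Leaving 2 of the 4.84 ug/L fish, the farthest on the concentration axis, out of the correlation gave r from 0.74 to 0.77. The component itself was still computed with them, so these values do not test the relation without those fish. Adjusting scores and concentration for slide gave r = 0.85. A slide holds 3 or 4 of these arrays, too few for a value within each. The groups overlapped on the first component of the 19 arrays. Its mean was -32.6 in controls, -46.4 at 0.69 ug/L, 0.3 at 1.37 ug/L, 26.4 at 2.56 ug/L and 58.8 at 4.84 ug/L. Control 2D4 scored 19.6, and the 1.37 ug/L fish ran from -40.2 to 43.4. The highest 2.56 ug/L fish, at 61.6, lay within the 46.5 to 66.6 of the 4.84 ug/L fish. Over all 20 arrays the first component had r = 0.50 (permutation p = 0.021, adjusted 0.032) and rho = 0.72 (permutation p = 0.00067, adjusted 0.002), and the second r = 0.64 (permutation p = 0.0026, adjusted 0.0077) and rho = 0.67 (permutation p = 0.002, adjusted 0.0031).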

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

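The tests of 11B2, 2D4 and 10C4 in this part were chosen after their results were seen, and those on other splits of the arrays before.

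The array of the 2.56 ug/L fish 11B2 stood far from the other arrays of its group, with 99.72% of probes well above background (86.21% to 88.23% on the others), an SD of log2 signals of 2 (2.85 to 2.93) and a mean rank correlation with its group of 0.9182 (0.949 to 0.952). The spike-in RNAs, which are added in the laboratory and enter no comparison, showed it too: the 3 dimmest averaged 5.30 on the log2 scale against 1.10 at most on the other 19 arrays, a gap of 4.20, while the 3 brightest averaged 12.41, within the 11.52 to 12.83 of the rest. As these RNAs are not made by the fish, a raised signal floor on that array is a candidate explanation for its dim probes. The exposure itself is argued against, since the other 3 arrays at 2.56 ug/L had at most 88.23% of probes well above background, below the 90.26% reached in the other groups. The spike-in RNAs next in brightness after the 3 dimmest read 5.34, 6.37 and 7.22 on 11B2. Each lay above the highest of the other 19 arrays (4.26, 5.72 and 7.15), so the effect reached beyond the dimmest signals. The 8366 brightest probes were little touched, with r = 0.982 against the mean of the other arrays, and r was 0.307 in the 8366 dimmest.

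The control 2D4 was placed at 0.68 on the held-out scale, near the 4.84 ug/L fish. A swap with 1 of them is argued against, since it would leave a 4.84 ug/L fish at the level of the other controls, and the lowest of them lay at 0.75 against 0.16 for the highest of the other controls. A swap with a 1.37 ug/L fish could not be excluded, as 10B3 lay at 0.11. A shift of its whole slide cannot be told apart from a property of the fish: the largest departure from group mates among the other 3 arrays of that slide (0.34, 11A3) was 52.3% of that of 2D4 (0.65), while 9D1 departed by 0.22 and 12A2 by -0.01, which shows no shift. A single wrong label, or fish that differ before any exposure, stay open as well and were not tested.

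On the array of the 1.37 ug/L fish 10C4, 203 probes lay over 16-fold below their median over all arrays, against 6 to 18 on the other arrays of the group. Of the low probes tested, 90.6% lay within 3 rows and columns of another on the array surface, against 11.8% to 27.1% (95% range) in 1000 random placements, so that a patch of low signal on the surface is a likely cause. A sequence difference under the probes in that fish would scatter them, and only 9.4% had none beside them. The probes around the patch read low on 10C4 (median log2 difference -2.07) and on 10D2 of the same slide (-0.66). On 11B2 the median was 0.68, and on the remaining 17 arrays it lay between -0.09 and 0.20. 

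Spots marked as outliers numbered 1125 on the 4.84 ug/L array 12A1, far from the 7 to 14 on the others of its group, and each of 4 equal sections along the array held 23.8% to 26.3% of those tested. The 0.69 ug/L array 9B3 had 16 such spots and the others of its group 1 or 2. In all, 55 groups of 4 values were examined by Dixon's ratio and 6 stood out, several of them through 11B2. Chance flags about 1 in 20 groups, here 2.8. Control 2D4 was not among those that stood out, though its held-out place and its values on the named probes were examined. Slide 3, which holds 2D4, carries in its file headers the identifier of slide 5, and whether the 8 arrays of both slides are assigned to the right fish is open. At positions 1 to 4, the places were 0.19 (9D1), 0.82 (12A2), 0.82 (11A3) and 0.68 (2D4) on slide 3 and -0.15 (2A1), 0.04 (9B1), 0.11 (10B3) and 0.61 (11D1) on slide 5.

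Differences between concentrations also stood out, tested directly by limma: 4323 probes differed between 4.84 and 0.69 ug/L and 310 between 2.56 and 0.69 ug/L.

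With no correction over the comparisons, chance alone is an unlikely source for the comparison of 4.84 ug/L with the controls. There the real grouping was the 1 split of 35 with as many probes (2141, and 57 in the highest other). The same held for 4.84 against 0.69 ug/L (4323 and 1) and 2.56 against 0.69 ug/L (310 and 2). For the trend (5558 and 209) and any difference (1772 and 8), the real order was the 1 of 100 with as many, the others being random. With 35 splits, a share of 1 is the least this test can give. The 310 calls are not secure all the same, with 0 after normexp, 3 after quantile normalisation, 0 with only the 8 arrays and 0 without 11B2, 9B1, 9D1, 10D2, 11D1, 12A2 or 12B4. For the other comparisons the count of splits says nothing on chance: with 0 probes in the real grouping, 35 of 35 splits must have as many. Their highest other splits gave 4 (0.69 ug/L against control), 496 (1.37), 289 (2.56), 4 (4.84 against 1.37), 19 (4.84 against 2.56), 27 (2.56 against 1.37) and 0 (1.37 against 0.69). The split with 496 probes exchanges 2D4 and 10B3, which points to a structure of these fish that the groups do not give. The split with 289 probes sets slides 1 and 5 (2A1, 2B1, 11B2, 11D1) against slides 3 and 4 (2C1, 2D4, 11A3, 11C4) and so follows the slides; with slide as a fixed block, 2.56 ug/L against control still gave 0 probes.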

How the results depend on the processing

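The fit without 11B2 and 10C4 together, that with the letter as a replicate block and the trend without the 4.84 ug/L arrays were chosen after the results were seen. The trend, the comparison of 4.84 ug/L with the controls and that with 0.69 ug/L had calls under each alternative that kept all arrays. Away from those within 1.5 times of the value reported, 4.84 ug/L against control gave 6468 probes with array weights, 557 with only the 8 arrays compared and 4358 at an adjusted p of 0.1. Array weights also gave 7275 (4.84 against 0.69 ug/L), 100 (4.84 against 1.37), 502 (2.56 against 0.69), 7 (1.37 against control), 9175 (trend) and 4714 (any difference). Any difference gave 1088 with slide as a fixed block and 3877 at an adjusted p of 0.1. For 2.56 against 0.69 ug/L, counts were 3 (quantile normalisation), 16 (median centring), 0 (normexp), 6 (no filter on dim probes), 1272 (slide as a random block), 0 (only the 8 arrays), 3 (the authors' table), 2644 (adjusted p of 0.1) and 0 (without 11B2 and 10C4 together). The trend gave 0 without the 4.84 ug/L arrays. Without 11B2 and 10C4, 4.84 ug/L against control gave 2873 probes and the trend 7090. These 2 counts were 2700 and 6103 with slide as a random block (correlation 0.1). With fish of a group with the same letter as a random block they were 2234 and 5702 (correlation -0.037). Within groups, only a pair of fish at 0.69 ug/L and a pair at 4.84 ug/L shared a letter. The correlation of that block rests on these pairs alone, so the fit cannot show whether the counts hold under blocking by letter.

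With each of the 20 arrays left out in turn, counts ran from 0 to 4205 (4.84 ug/L against control), 0 to 309 (2.56), 0 to 23 (1.37), 0 to 2 (0.69), 2295 to 5252 (4.84 against 0.69 ug/L), 0 to 5 (4.84 against 1.37), 0 to 1 (4.84 against 2.56), 0 to 2450 (2.56 against 0.69), 0 to 3 (2.56 against 1.37), 0 to 43 (1.37 against 0.69), 3373 to 6899 (trend) and 0 to 3108 (any difference). With controls split 2 and 2, the correlation of changes moved on average to -0.105 (0.69 and 1.37 ug/L), -0.274 (0.69 and 2.56), 0.183 (1.37 and 2.56), 0.294 (1.37 and 4.84) and 0.404 (2.56 and 4.84). Part of this follows from the shared controls; where no cause is named, the cause was not tested.

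The log2 changes of the 4 named probes at 4.84 ug/L had the same sign in all fits, and those of both falls shrank by over 1.5 times after normexp, to -2.61 and -2.43. With the authors' table the 4 changes were 5.25, 5.19, -4.23 and -3.95, the same as after quantile normalisation. These 2 alternatives may therefore not be separate checks. Apart from fits without 1 array, CUST_16659_PI428861894 missed the threshold of limma's test after normexp (adjusted p = 0.057), without a filter (0.051), with only the 8 arrays (0.065) and with the letter as a replicate block (0.063), with adjusted p from 0.0042 to 0.15 over all its alternatives. The full replicate codes are not shared between groups, but the letters A to D in them are. With the letter as a fixed replicate block, 4.84 ug/L against control gave 2163 probes, the trend 5264, 4.84 against 0.69 ug/L 3486, 2.56 against 0.69 ug/L 0 and any difference 825, and CUST_1082_PI428861894 and CUST_16659_PI428861894 had limma adjusted p of 0.055 and 0.063 at 4.84 ug/L. The letters did not pair the fish: deviations from the group means correlated by 0.006 on average over the 40 pairs with the same letter (over 0.1 in 9), by -0.002 over the others, and 5 of 20 arrays correlated best with their own letter. The gene list alternatives were not run, as no probe has a gene name. Of the 8366 dimmest probes 1.8% were called, with a median residual SD of 0.56, and the reason for the low share was not tested.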

Other observations

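The measures in this part were chosen after the data were seen. Probes with consecutive numbers rose and fell together across the 20 fish, with a median correlation of 0.63 over 5000 pairs, against 0.07 for probes 50 numbers apart. Of 2068 probes called at 4.84 ug/L whose next number was tested, 902 (43.6%) had a next number called in the same direction and 21 in the opposite one. Over 1000 shuffles of the calls the first share averaged 3.2% and reached 4.4% at most. The counts of called probes are therefore not counts of independent measurements.

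Of 32310 probes measured on all arrays, 89 split the fish into levels at least 2 log2 units apart with at least 4 fish on each side. Of these, 63 had a neighbour in number with the same property, and together they made 45 distinct splits of the fish. Of the 89 probes, 6 passed limma's trend test at an adjusted p of 0.05, which 16.6% of all tested probes passed. As groupings of fish, none of the 45 splits was associated with concentration after adjustment (exact permutation test of the mean concentration, two-sided, lowest p = 0.0052, lowest adjusted p = 0.23). The split with the lowest p was shared by 6 probes and had 3 of 4 controls, 4 of 4 fish at 0.69 ug/L, 1 of 4 at 1.37 ug/L, 1 of 4 at 2.56 ug/L and 0 of 4 at 4.84 ug/L at the high level. Whether these are the 6 probes that passed the trend test was not examined.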
